A study of Mus musculus with 40 samples.

How the data were processed

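RNA from the epididymal white adipose tissue, the fat pad that lies along the testis and epididymis, was measured in 40 male C57BL/6J wildtype mice on Agilent 4x44K mouse arrays. Per the labels, the mice ate a purified low-fat diet (LFD) or high-fat diet (HFD) without restriction for 5 days or for 12 weeks, with 10 animals in each of the 4 groups, and were fasted for 2 hours before tissue was taken. From each animal 1000 ng of RNA was labelled with Cy5 and hybridised against a Cy3-labelled pool made from equal amounts of all samples. No array had the dyes swapped, so a dye effect of a probe is shared by every array and drops out of a difference between groups. The arrays came on 10 slides of 4 arrays, each slide holding 1 array of every group, and the replicate number in the labels is the slide. The file headers give 1 scan day for all 40 arrays.

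The deposited scanner files hold, for each spot, the intensity of the red (Cy5) and green (Cy3) channels and of the local background on a linear scale. They were extracted with Agilent Feature Extraction 10.5.5.1 per the submitters' processing notes and 10.5.1.1 per the file headers. The same deposited files hold a log10 ratio of Cy5 to Cy3 after the scanner software's own background and dye corrections, per the file headers, which served as an alternative. A deposited series table gives values on what appears to be a log2 scale for 25150 features, 58.5% of the spots, with a median of 8.42 in each of the 40 columns. Its values correlated with the log2 red intensity across probes of an array at r = 0.981 to 0.998 and with the log ratio at r = 0.137 to 0.231. The deviations of each probe from its mean over arrays followed the log ratio (r = 0.923) more closely than the red channel (r = 0.487). How the authors centred that deposited table, and whether they corrected it for the reference channel, is not stated, so it too served only as an alternative. The design of the arrays places its probes on the mm9 mouse genome, and the positions given are those of the probes.

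The spot intensities were processed in R 4.3.3 with limma 3.58.1, jsonlite 2.0.0 and the data.table package in version 1.17.8. Background was subtracted with the normexp method and an offset of 50, the log2 ratio of red to green was normalised within each array by loess, and replicate spots of a probe were averaged. Each array has 43020 spots of 39429 probes besides 1377 control spots, which were not used. The 0.493% of spot values that the scanner software marked as uneven or as deviating from their replicate spots were set aside. A probe was kept if its red signal was well above background on at least 10 of the 40 arrays, which left 28301 probes. Probes were named from the given gene tables by accession (26412 probes), symbol (3854) or synonym (735), and 8428 kept the name in the file. For the 4623 genes with several probes, the probe with the highest mean intensity was used. In all, 22751 genes were tested, of which 15810 had a gene symbol. Crygc, Mfsd2a, Atp6v0d2 and Ucp1, given with values in the report, were well above background on 8 to 10 of the 10 arrays of each group compared. The number of arrays limits the precision of every estimate.

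A linear model with 1 mean per group was fitted to each gene by limma with empirical Bayes moderation. The 5 comparisons read from it were HFD minus LFD at 5 days, HFD minus LFD at 12 weeks, the difference between these diet effects (the interaction), and 12 weeks minus 5 days on each diet. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called when its adjusted p was below 0.05. Errors of log2 fold changes are standard errors from the fit with n = 10 per group, and errors of group means are standard deviations. Beside a gene, the number of slides that showed the direction is the number of slides on which the array of the first group lay above, or below, that of the second.

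The comparisons, the 39 gene lists and the alternatives were fixed before the data were examined. Genes named in the text followed a rule fixed then. They are the 8 highest and 8 lowest log2 fold changes among called genes with a gene symbol in each diet comparison, and 5 and 5 in the other comparisons. To these were added up to 4 called members per list with the largest change, and 14 genes that are always given (Lep, Mest, Npr3, Sfrp5, Adipoq, Pparg, Slc2a4, Scd1, Fasn, Hmgcs1, Adgre1, Itgax, Ccl2 and Ucp1). The result of 1 gene that the rule names is not reported here. The 22 pathway lists cover de novo lipogenesis, cholesterol synthesis, triglyceride synthesis and lipid droplets, lipolysis, fatty acid uptake and transport, fatty acid oxidation, the TCA cycle and oxidative phosphorylation, branched-chain amino acid breakdown, glucose uptake and insulin signalling, and adipokines. They also cover fat expansion genes, extracellular matrix, chemokines, cytokines and acute phase, class II antigen presentation, interferon response, lysosome, unfolded protein response, hypoxia response, oxidative stress defence, circadian clock, cell cycle and immediate early genes. The 17 cell lists hold markers of mature adipocytes, brown and beige adipocytes, adipose progenitors and fibroblasts, macrophages, lipid-associated macrophages, resident macrophages, T and NK cells, B and plasma cells, neutrophils, mast cells, endothelial, mural and mesothelial cells, epididymis, testis germ cells, skeletal muscle and erythroid cells. Lists were written from general knowledge of the genes and share some members.

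A list was tested against all other genes with camera at a preset correlation between genes of 0.01, adjusted over the 39 lists of a comparison. Each was tested again with the correlation estimated from the data and with fry, which asks only whether the genes of a list move in 1 direction. For each list the number of members past the test over all genes and adjusted over the list alone was counted. Agreement between the diet effects at the 2 durations was measured by the correlation across genes, which are not independent replicates, and by the overlap of calls. The diet groups were also regrouped 100 times within each duration. A signature score of an animal was the mean log2 ratio of genes called higher minus that of genes called lower in the comparison of the other duration, fitted on the arrays of that duration alone. Scores were compared by a two-sided permutation test with 100000 resamples. Relations between the macrophage list and Lep, Mest or the mature adipocyte list across the 10 animals of a group, 12 relations in all, were tested by Pearson and Spearman correlation with permutation p-values adjusted over the 12.

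The pipeline was tested on simulated data, independent random normal values with the spread of each gene in this study, to which known changes were added in 67 genes at log2 0.25, 67 at 0.5 and 66 at 1. Of the genes changed by 0.5, 91.0% were called in the 5-day diet comparison, 92.5% in the 12-week diet comparison and 82.1% in the interaction, and at 0.25 these shares were 53.7%, 46.3% and 26.9%. Between 1.46% and 5.06% of calls were false. Of 30 simulated lists of 20 genes, the list shifted by 0.3 was called (camera adjusted p = 5.5e-61) and 0 of the unshifted lists were. Genes on the real arrays vary together, which the simulation leaves out. Its shares of false calls and its list result therefore need not hold for these data.

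Alternatives were the scanner software's log ratio, no background subtraction, A-quantile normalization, scale normalization between arrays, the red channel alone, no filter, and a filter on 36 of the 40 arrays. Others were the replicate number as a block, the block with the position of the array on the slide, array weights, a trended and robust prior, the mean of a gene's probes, every probe tested, a fit on only the groups compared, the series table, and leaving out each slide. Chosen after the data had been seen were fits without the 12 arrays that carried epididymis transcripts (list mean above -1.5), without those and the arrays with testis germ cell transcripts (list mean above 0), with both list means as covariates, with the mean of probes holding a run of at least 5 CA or TG units as a covariate, without those probes, and leaving out each of the 40 arrays, for the gene counts and for the list shifts. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9 and numpy 2.4.6. No array was left out of the main results.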

Results

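Gene expression in epididymal white adipose tissue was measured in 40 male mice, 10 on LFD for 5 days, 10 on HFD for 5 days, 10 on LFD for 12 weeks and 10 on HFD for 12 weeks. The study's question was how far the changes that a high-fat diet brings within days resemble those after weeks. Each array compared 1 animal (Cy5) with a pool of all animals (Cy3). The median red signal above background was 45.5 to 123 intensity units per array (median 82.1). The share of probes well above background in red was 66.4% ± 3.9, 67.0% ± 4.5, 65.4% ± 4.7 and 67.7% ± 2.4 (SD, n = 10 each) in the order of the groups above. No pair of arrays was identical, and the highest correlation between any 2 arrays was 0.853. After 5 days, 297 of 22751 genes differed between the diets, and after 12 weeks 4329 did.

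After 5 days of HFD, 63 genes were higher and 234 lower than on LFD, so 78.8% of the changes were decreases, and 20 genes changed more than 2-fold, 17 of them downward. Of those called that had a gene symbol, 60 were higher and 125 lower. The largest decreases were in enzymes that make fatty acids from sugar. Acly, which makes cytosolic acetyl-CoA from citrate, had a log2 fold change of -2.53 ± 0.23 (SE, n = 10 per group, adjusted p = 1.73e-09, lower on 10 of 10 slides), measured by a probe at chromosome 11, 100337674 to 100337733 (mm9). The acetyl-CoA synthetase Acss2 changed by -2.16 ± 0.22 and the elongase Elovl6 by -2.12 ± 0.18 (adjusted p = 1.11e-09, chromosome 3, 129341248 to 129341307). Fasn, the fatty acid synthase, changed by -1.98 ± 0.22 (adjusted p = 1.8e-07, chromosome 11, 120667666 to 120667725). Me1 (-1.82 ± 0.21) and Tkt (-1.73 ± 0.18), which supply NADPH and its pathway's sugars, Acaca (-1.66 ± 0.16), the carboxylase that commits carbon to fatty acids, and the glycogen synthase Gys2 (-1.41 ± 0.29) followed. Other probes of a gene could give smaller decreases, down to -1.19 for Acly, -1.05 for Acaca and -0.67 for Gys2. The insulin-regulated glucose transporter Slc2a4 fell by 0.40 ± 0.10 (adjusted p = 0.0285, 10 of 10 slides) and the desaturase Scd1 by 0.90 ± 0.19 (adjusted p = 0.00722, 10 of 10 slides).

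The largest increase at 5 days was in the membrane protein Emp1, 1.39 ± 0.15 (adjusted p = 7.24e-08, higher on 10 of 10 slides, chromosome 6, 135333061 to 135333120). Mest, an imprinted gene that tracks fat expansion, rose by 1.22 ± 0.24 (adjusted p = 0.00347, 10 of 10 slides), and Trp53inp2 by 1.07 ± 0.16 (adjusted p = 0.000102). The lowest value among the 3 Mest probes was 0.51. The acute-phase gene Hp (0.89 ± 0.17), Pmepa1 (0.87 ± 0.14), the complement gene C4b (0.75 ± 0.20) and Lrg1 (0.70 ± 0.18) also rose. Lep, the leptin gene, had a value of 0.77 ± 0.25 and was higher on 9 of 10 slides but did not pass (adjusted p = 0.148). The values for Npr3 (0.43 ± 0.19), Sfrp5 (0.33 ± 0.23), Adipoq (0.11 ± 0.14), Pparg (-0.11 ± 0.10), Hmgcs1 (0.23 ± 0.20) and Ucp1 (-0.08 ± 0.69) did not pass. Nor did those for the macrophage genes Adgre1 (0.31 ± 0.11) and Itgax (0.24 ± 0.10) and the chemokine Ccl2 (0.36 ± 0.19). The number of calls depended on the processing: it was 873 with array weights, 474 with the mean of CA or TG repeat probes as a covariate, 19 with scale normalization between arrays, where of the named genes only Pdk1 kept its call, and 90 from the red channel alone. It was 89 without the 12 arrays that carried epididymis transcripts, and 119 at the lowest when 1 slide was left out.

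Of the 39 gene lists, 16 shifted at 5 days, 10 upward and 6 downward, and only de novo lipogenesis held with an estimated correlation between genes. In that list 11 of 16 genes fell (13 adjusted over the list alone), with a median of -1.20 (adjusted p = 1.19e-40, and 0.000111 with an estimated correlation). In cholesterol synthesis 6 of 25 genes fell (13 adjusted over the list alone), with a median of -0.36 (adjusted p = 2.3e-12, and 0.102 with an estimated correlation). Pmvk (-0.82 ± 0.16), Fdps (-0.73 ± 0.16), Nsdhl (-0.71 ± 0.13) and Idi1 (-0.59 ± 0.15) fell most. The other Nsdhl probe gave -0.30. In the TCA cycle and oxidative phosphorylation list 6 of 23 fell (17 adjusted over the list alone), among them Ndufs1 (-0.37 ± 0.07) and Cycs (-0.36 ± 0.09), with a median of -0.22 (adjusted p = 2.32e-20, and 0.0808 with an estimated correlation). The smallest decrease among the 3 Cycs probes was -0.05. Fatty acid oxidation (median -0.13) and branched-chain amino acid breakdown (-0.16) also shifted down (adjusted p = 0.436 and 0.185 with an estimated correlation), as did the 5 erythroid genes (-0.28, adjusted p = 0.297 with an estimated correlation).

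Among the upward lists, 2 of 11 fat expansion genes rose (6 adjusted over the list alone), Mest and Cavin1 (0.43 ± 0.11), with a median of 0.43 (adjusted p = 9.06e-09, and 0.102 with an estimated correlation). The other Cavin1 probe gave 0.11, and with the slide as a block in limma Cavin1 did not pass (adjusted p = 0.0561). In the extracellular matrix list 2 of 28 rose, Fn1 (0.54 ± 0.14) and Col1a1 (0.53 ± 0.13), and 14 did adjusted over the list alone (median 0.24, adjusted p = 1.12e-11, and 0.102 with an estimated correlation). With the slide as a block in limma Fn1 did not pass (adjusted p = 0.0507). The chemokine, cytokine and acute-phase list (median 0.17, 1 of 22 rose) and the class II antigen presentation list (0.21, 0 of 10) shifted up, with adjusted p = 0.102 and 0.264 with an estimated correlation. The macrophage (0.18), lipid-associated macrophage (0.14), resident macrophage (0.21), and adipose progenitor and fibroblast (0.19) lists shifted up with no member past the test over all genes (adjusted p = 0.234, 0.297, 0.185 and 0.134 with an estimated correlation). Much of several of these shifts came from 1 animal, 5-day LFD replicate 5. Without its array the medians were 0.10 for macrophages, 0.099 for resident macrophages, 0.11 for progenitors and fibroblasts, 0.13 for class II genes and 0.11 for chemokines, cytokines and acute phase, each still past the test (adjusted p = 0.00315, 0.00311, 0.00395, 0.0323 and 0.000894). The cell cycle list shifted by a median of 0.11 with no member past the test, and the immediate early genes by 0.08 with 1, Jun (0.50 ± 0.09), past it (adjusted p = 0.392 and 0.152 with an estimated correlation). The cell cycle shift rested on 5-day HFD replicate 7, without which the median was 0.044 and did not pass (adjusted p = 0.052). The immediate early median was 0.11 or 0.12 without 5-day LFD replicate 2 or 6. The hypoxia list did not shift by camera (median 0.0097 but mean -0.05, adjusted p = 0.203), although fry called it lower (adjusted p = 0.0333). Its member Pdk1 fell by 0.75 ± 0.10 and Bnip3 rose by 0.41 ± 0.11, where Bnip3 did not pass in limma with the slide as a block (adjusted p = 0.0507). Plin4, which coats lipid droplets, rose by 0.59 ± 0.12, and Rbp4 fell by 0.66 ± 0.16. Neither of their lists shifted (adjusted p = 0.0716 for triglyceride synthesis, 0.537 for adipokines). Oxidative stress defence did not shift by camera (adjusted p = 0.0761), but fry called it lower (adjusted p = 0.0333). Fry did not call several lists that camera did. They were macrophages (adjusted p = 0.0948), lipid-associated macrophages (0.14), resident macrophages (0.0688), class II genes (0.112) and cell cycle (0.24). Fatty acid oxidation (0.261), branched-chain amino acid breakdown (0.0531) and erythroid genes (0.128) were not called by fry either.

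After 12 weeks of HFD, 2114 genes were higher and 2215 lower than on LFD, and 127 changed more than 2-fold, 97 of them downward. Sfrp5, a secreted Wnt inhibitor that rises in growing fat, had the largest increase, 2.89 ± 0.23 (adjusted p = 1e-11, higher on 10 of 10 slides, chromosome 19, 42272509 to 42272568). The matrix protein Thbs1 rose by 2.68 ± 0.24 (adjusted p = 1.16e-10, 10 of 10 slides, chromosome 2, 117952585 to 117952644). Ifi27l2a (1.86 ± 0.20), Emp1 (1.80 ± 0.15), C4b (1.63 ± 0.20), Nnat (1.63 ± 0.21), Ankrd29 (1.61 ± 0.16) and Mest (1.61 ± 0.24) completed the 8 largest. Lep rose by 1.21 ± 0.25 (adjusted p = 0.00045, 9 of 10 slides, chromosome 6, 29023234 to 29023293), and the natriuretic peptide clearance receptor Npr3 by 0.75 ± 0.19 (adjusted p = 0.00362). The largest decreases were in Elovl6 (-3.25 ± 0.18, adjusted p = 1.04e-15), Acly (-3.11 ± 0.23, adjusted p = 1.72e-12), Acss2 (-2.85 ± 0.22), Fasn (-2.45 ± 0.22) and Gys2 (-2.29 ± 0.29). Scd1 fell by 1.69 ± 0.19, Slc2a4 by 0.83 ± 0.10 and the adipocyte regulator Pparg by 0.41 ± 0.10 (adjusted p = 0.00345). Adipoq (0.32 ± 0.14), Hmgcs1 (0.16 ± 0.20) and Ucp1 (-0.41 ± 0.69) did not pass. Crygc (-2.46 ± 0.84), Ptgs2 (-2.42 ± 0.84) and Fxyd4 (-2.30 ± 0.80) were also among the 8 lowest but were lower on only 7 of 10 slides. Without the 12 arrays that carried epididymis transcripts their values were -0.28, -0.21 and -0.39 (adjusted p = 0.592, 0.808 and 0.502). The Ptgs2 probe was well above background on 5 of 10 LFD and 8 of 10 HFD arrays. Without those 12 arrays, 6 of them from the 12-week LFD group, 2007 genes differed at 12 weeks (62.2% lower, against 51.2% with all arrays), and without these and the germ cell arrays 2533. There were 2255 from the red channel alone and 2643 with scale normalization.

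Metabolic lists mostly shifted downward at 12 weeks. In de novo lipogenesis 15 of 16 genes fell (16 adjusted over the list alone), with a median of -1.68 (adjusted p = 2.43e-28, and 0.00185 with an estimated correlation). The list's mean log2 ratio was -1.04 ± 0.11 on HFD and 0.65 ± 0.41 on LFD (SD, n = 10). In cholesterol synthesis 20 of 25 fell and 1 rose, the same numbers adjusted over the list alone (median -0.68, adjusted p = 4.65e-18, and 0.0293 with an estimated correlation). Insig1 (-1.75 ± 0.22), Pmvk (-1.43 ± 0.16), Lss (-1.29 ± 0.17) and Tm7sf2 (-1.28 ± 0.20) fell most. All 23 genes of the TCA cycle and oxidative phosphorylation list fell, with a median of -0.50 (adjusted p = 1.1e-24, and 0.0293 with an estimated correlation). Among them were Cycs (-0.72 ± 0.09), Cox5a (-0.72 ± 0.07), Cox6a1 (-0.65 ± 0.07) and Cs (-0.57 ± 0.07). In fatty acid oxidation 12 of 19 fell (14 adjusted over the list alone), among them Slc25a20 (-0.53 ± 0.10) and Hadha (-0.47 ± 0.11), with a median of -0.32 (adjusted p = 2.33e-06, and 0.204 with an estimated correlation). In branched-chain amino acid breakdown 8 of 17 fell (10 adjusted over the list alone), with a median of -0.27 (adjusted p = 5.45e-06, and 0.171 with an estimated correlation). In oxidative stress defence 9 of 17 fell and 2 rose (median -0.24, adjusted p = 0.0089, and 0.0293 with an estimated correlation). Srxn1 (-0.50 ± 0.13) and Gsta4 (-0.47 ± 0.06) were lower but Sod3 (0.71 ± 0.11) was higher. The shift was -0.11 (adjusted p = 0.21) from the red channel alone.

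Some lipid-handling lists held changes in both directions and did not shift. In triglyceride synthesis and lipid droplets 3 genes rose and 6 fell (median -0.14, adjusted p = 0.36), with Cidea (-2.12 ± 0.35) and Agpat2 (-1.29 ± 0.22) lower and Plin4 (0.90 ± 0.12) and Hilpda (0.70 ± 0.08) higher. In lipolysis Abhd5 fell by 0.49 ± 0.09 and Aqp7 rose by 0.34 ± 0.12 (list adjusted p = 0.599), and in fatty acid uptake Fabp5 fell by 1.30 ± 0.19 and Acsl1 by 0.51 ± 0.13 (0.37). Glucose uptake and insulin signalling (3 of 15 higher, 3 lower, adjusted p = 0.574) held Trarg1 (0.58 ± 0.14) and Irs2 (0.50 ± 0.13) among the higher. Adipokines (3 of 11 higher, 3 lower, 0.362) held Rbp4 (-0.70 ± 0.16) and Retn (-0.45 ± 0.15) among the lower. The mature adipocyte list did not shift (median -0.10, adjusted p = 0.453), with 2 of 13 higher and 2 lower. In the brown and beige adipocyte list 5 of 12 fell, among them Cox8b (-1.91 ± 0.30) and Ppargc1a (-0.66 ± 0.13), with a median of -0.38 (adjusted p = 0.00516, and 0.371 with an estimated correlation). That median was -0.11 (adjusted p = 0.14) without the arrays that carried epididymis transcripts and -0.14 (adjusted p = 0.0244) without 12-week LFD replicate 10. In the hypoxia response 3 genes rose and 4 fell (median -0.13, camera adjusted p = 0.205), Pdk1 (-1.01 ± 0.10) and Egln3 (-0.80 ± 0.10) among the lower. By fry that list was called lower (adjusted p = 7.92e-06).

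**Figure D1:**
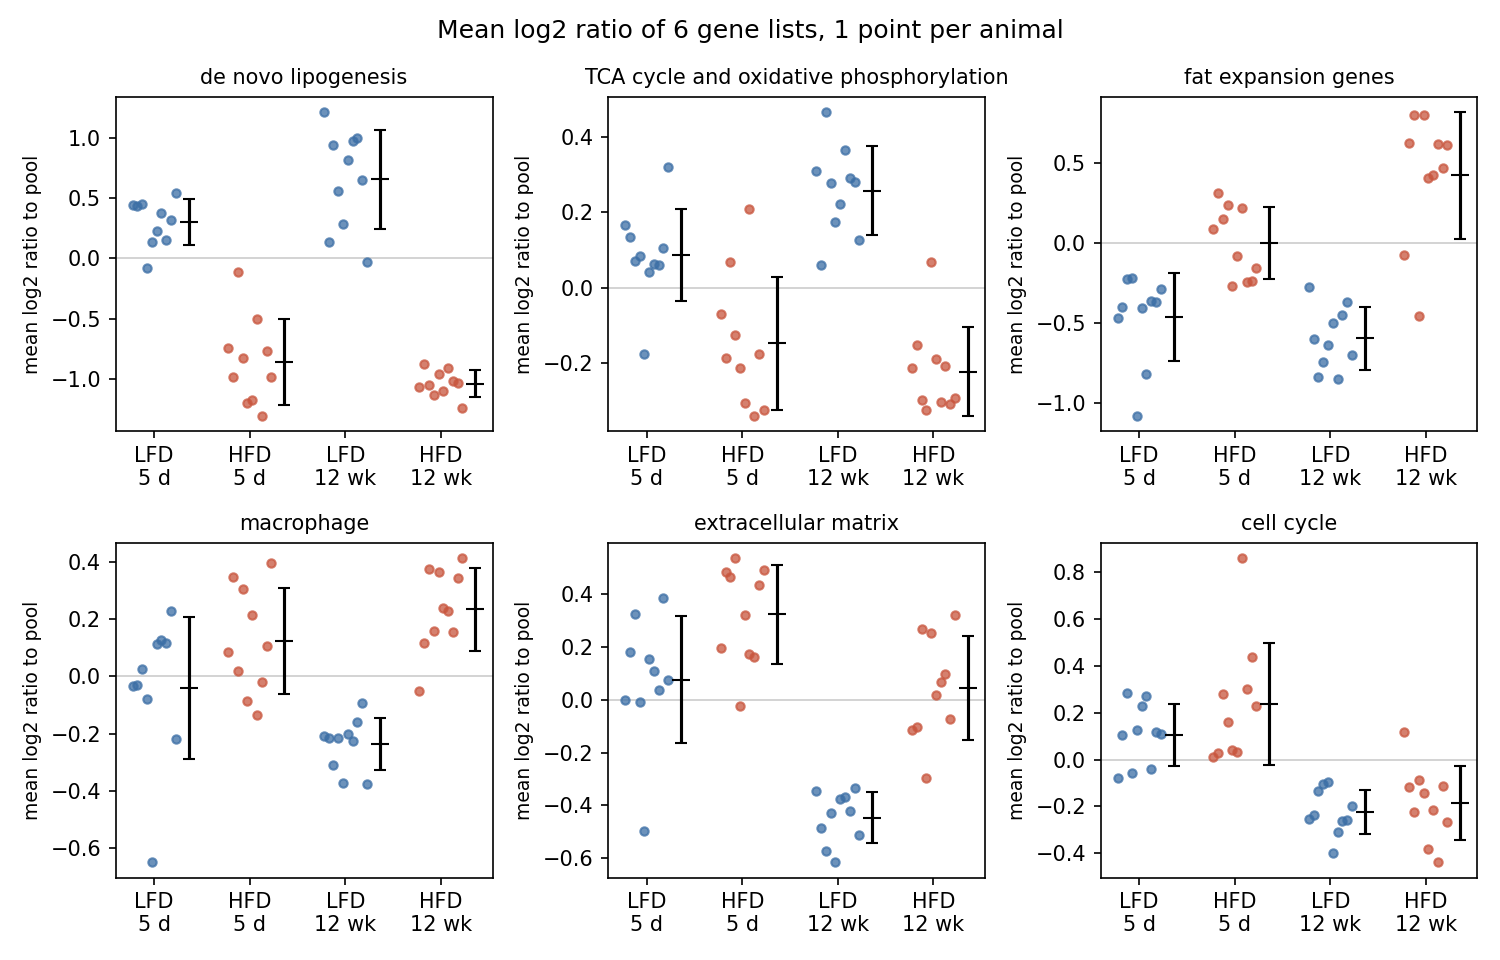
Mean log2 ratio to the pool of all animals for 6 gene lists, with 1 point per animal, 4 groups per panel and bars at the mean ± SD (n = 10). De novo lipogenesis means were 0.30 ± 0.19 on LFD and -0.86 ± 0.36 on HFD at 5 days, and 0.65 ± 0.41 and -1.04 ± 0.11 at 12 weeks.

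Immune, matrix and expansion genes shifted upward at 12 weeks. In the macrophage list 13 of 18 genes rose, the same number adjusted over the list alone, with a median of 0.53 (adjusted p = 9.92e-11, and 0.068 with an estimated correlation). Adgre1 (0.61 ± 0.11, adjusted p = 0.000117), Tyrobp (0.72 ± 0.10) and Lyz2 (0.61 ± 0.13) were among them. In the lipid-associated macrophage list 10 of 14 rose, among them Itgax (0.78 ± 0.10), Gpnmb (0.94 ± 0.15) and Trem2 (0.72 ± 0.14), with a median of 0.45 (adjusted p = 6.15e-08, and 0.0293 with an estimated correlation). Its member Fabp5, which adipocytes also express, fell. In the resident macrophage list 11 of 14 rose and 1 fell, Retnla (1.08 ± 0.13), Lyve1 (0.82 ± 0.13), Cd209f (0.70 ± 0.11) and Folr2 (0.67 ± 0.12) most (median 0.49, adjusted p = 0.068 with an estimated correlation). Of 22 chemokine, cytokine and acute-phase genes 9 rose and 1 fell, Ccl9 (1.13 ± 0.15), Ccl7 (1.09 ± 0.15) and Ccl2 (1.09 ± 0.19) most (median 0.22, adjusted p = 0.0819 with an estimated correlation). Without the arrays that carried epididymis transcripts Ccl2 had a value of 0.75 (adjusted p = 0.0621). Among class II genes 6 of 10 rose, Cd74 (0.66 ± 0.21), H2-Aa (0.63 ± 0.13) and H2-Ab1 (0.61 ± 0.12) most (median 0.48, adjusted p = 0.171 with an estimated correlation). Of 20 lysosome genes 7 rose and 1 fell (median 0.17, adjusted p = 0.229 with an estimated correlation), Ctss (0.94 ± 0.14) and Ctsk (0.52 ± 0.12) higher and Ctsd (-0.53 ± 0.18) lower.

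Of 11 fat expansion genes 9 rose (10 adjusted over the list alone), with a median of 0.82 (adjusted p = 1.61e-10, and 0.0293 with an estimated correlation). In the extracellular matrix list 14 of 28 rose (18 adjusted over the list alone), among them Fn1 (1.09 ± 0.14), Fbn1 (0.86 ± 0.15) and Loxl2 (0.70 ± 0.11), with a median of 0.39 (adjusted p = 0.0749 with an estimated correlation). The adipose progenitor and fibroblast list (6 of 13 higher, 9 adjusted over the list alone, median 0.32) held Mfap5 (0.60 ± 0.11) and Pdgfra (0.33 ± 0.10), with adjusted p = 0.158 with an estimated correlation. The unfolded protein response (5 of 14 higher, median 0.26, Sdf2l1 0.65 ± 0.13, Hspa5 0.42 ± 0.11) and the immediate early genes (5 of 14 higher, median 0.20, Jun 0.77 ± 0.08, Atf3 0.75 ± 0.09, Klf4 0.71 ± 0.11) shifted up, with adjusted p = 0.158 and 0.0749 with an estimated correlation. The T and NK cell list shifted by a median of 0.11 with 1 gene, Cd2 (0.52 ± 0.09), past the test (adjusted p = 0.297 with an estimated correlation). The interferon list did not shift (median -0.04 but mean 0.08, adjusted p = 0.828), with Ifi27l2a (1.86, its highest value) and Oas2 (0.32 ± 0.11) higher and Rsad2 (-0.35 ± 0.12) lower. Neither did the circadian clock (adjusted p = 0.53, Tef 0.51 ± 0.18 and Per2 0.42 ± 0.08 higher) or the cell cycle list (median 0.02, adjusted p = 0.655). The B and plasma cell (adjusted p = 0.205), neutrophil (0.303), mast cell (0.944), endothelial (0.442), mural (0.0619), mesothelial (0.384), epididymis (0.309), testis germ cell (0.134), skeletal muscle (0.964) and erythroid (0.804) lists did not pass by camera. By fry the neutrophil list was called higher (adjusted p = 0.0164) and the mural list lower (adjusted p = 0.0239).

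Some samples carried transcripts of tissue next to the fat pad. The epididymis list, 10 genes of which none is in another list, had a mean log2 ratio above -1.5 on 6 of 10 arrays of the 12-week LFD group and on 2 of 10 in each other group. On those 12 arrays the sperm-coating gene Crisp1 had a mean log2 ratio of 0.39 against -5.55 on the other 28, and Spink8 0.47 against -4.49, with red signals up to 14.8 and 15.8 on the log2 scale. The testis germ cell list was above 0 on 5 arrays of the 12-week HFD group, 3 of the 12-week LFD group, 1 of the 5-day LFD group and 0 of the 5-day HFD group. Between those 9 arrays and the other 31 the protamine gene Prm2 had means of 1.53 and -1.89. Separately, 236 probes with a run of CA or TG units rose and fell together within groups (median correlation with their mean 0.926, against -0.026 for other probes). Their mean log2 ratio was 0.50 ± 0.27 and 0.41 ± 0.30 at 5 days on LFD and HFD and -0.06 ± 0.27 and 0.21 ± 0.35 at 12 weeks (SD, n = 10).

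**Figure D2:**
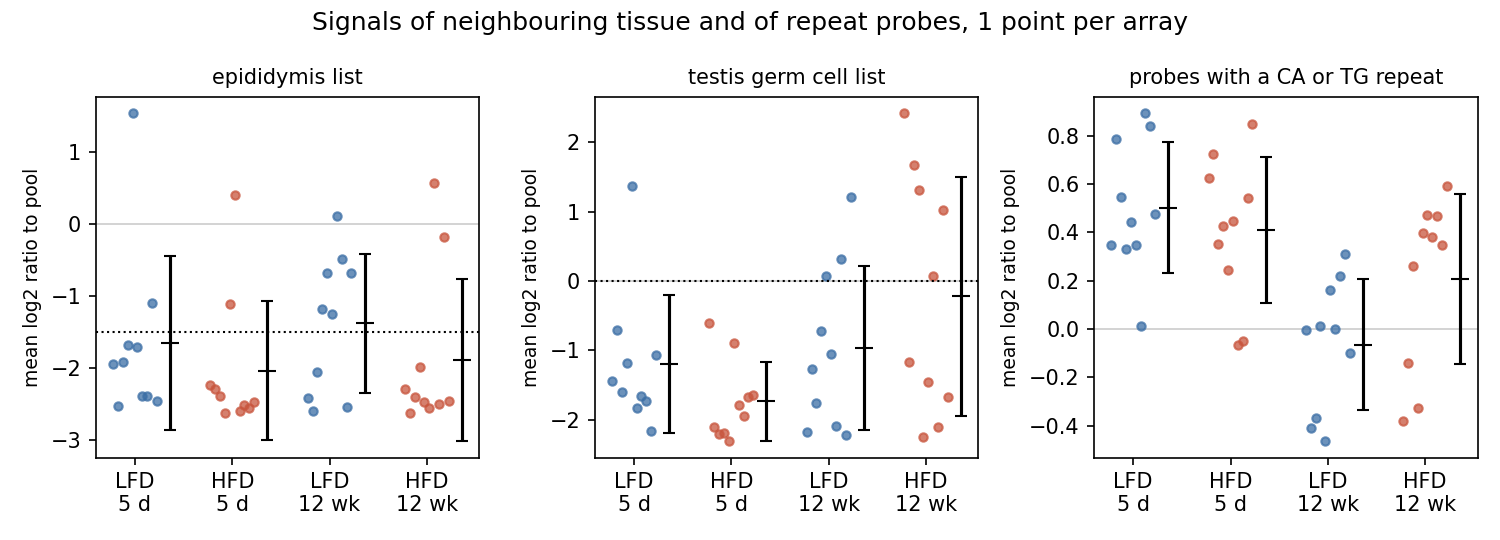
Mean log2 ratio to the pool for the epididymis list, the testis germ cell list and probes with a CA or TG repeat, with 1 point per array, 4 groups per panel, bars at the mean ± SD (n = 10) and dotted lines at -1.5 and 0 where arrays were counted as carrying the transcripts. The 12-week LFD group has 6 arrays above the epididymis line and the 12-week HFD group 5 above the germ cell line.

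The diet effects at 5 days and 12 weeks shared direction for nearly every gene that had changed early. Of the 297 genes called at 5 days, 294 had the same sign at 12 weeks (99.0%) and 286 were called in the same direction (96.3%). They were 56 genes higher at both against 5.85 by chance and 230 lower at both against 22.8. None was called in opposite directions. In the other direction, 6.61% of the 4329 genes called at 12 weeks were called at 5 days, and 81.3% had the same sign at 5 days against 55.9% of all genes. Of the 127 that changed more than 2-fold at 12 weeks, 61 were called at 5 days. Across all genes, which are not independent replicates, the effects correlated at r = 0.347 (Spearman 0.219), and 26 of 100 regroupings of the animals within each duration gave an r as large in size. Leaving out 1 slide gave r = 0.178 to 0.461, and the scanner software's ratio gave 0.0451. Among the 5-day calls r was 0.943, a value that selection on the 5-day effect can raise.

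**Figure D3:**
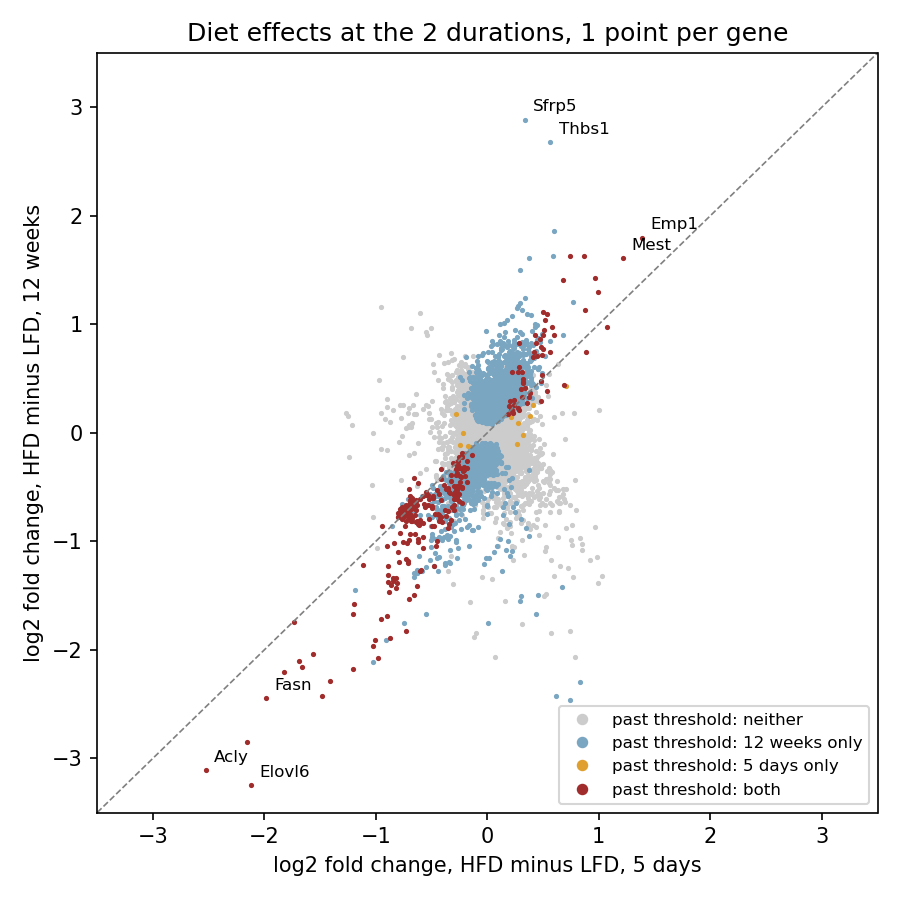
Log2 fold change of HFD over LFD at 5 days (x axis) and at 12 weeks (y axis), with 1 point per gene tested, coloured by the durations at which the gene was called, and a dashed line of equal change. Acly, Elovl6 and Fasn lie at the lower left and Emp1 and Mest at the upper right, while Sfrp5 (0.33 and 2.89) lies far above the dashed line.

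Scores of individual animals compared the durations animal by animal. Genes called from the 5-day arrays alone (30 higher, 142 lower) gave the 12-week animals a mean score of 0.80 ± 0.13 on HFD and -0.88 ± 0.33 on LFD (SD, n = 10 each, permutation p = 3e-05). The lowest HFD score, 0.64, lay above the highest LFD score, -0.32. Genes called from the 12-week arrays alone (1958 higher, 1915 lower) gave the 5-day animals 0.23 ± 0.12 on HFD and -0.06 ± 0.10 on LFD (SD, n = 10 each, permutation p = 8e-05). HFD was higher on 10 of 10 slides, and the area under the curve was 0.98.

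The size of the diet effect differed between the durations for 144 genes, 84 with a more positive effect at 12 weeks and 60 with a more negative effect. Of these, 141 had the larger effect at 12 weeks, 125 were called only at 12 weeks and 19 were also called at 5 days. Sfrp5 (2.55 ± 0.33, adjusted p = 4.85e-05, 10 of 10 slides) and Thbs1 (2.11 ± 0.34, adjusted p = 0.0016) had the largest positive differences, followed by Ifi27l2a (1.26 ± 0.29), Ankrd29 (1.24 ± 0.22) and Prr32 (1.21 ± 0.24). Such a difference can come from a change with time on either diet. The mean log2 ratio of Sfrp5 went from -1.65 to 1.17 on HFD and from -1.98 to -1.72 on LFD. That of Ifi27l2a was 0.72 and 0.67 on HFD but went from 0.12 to -1.19 on LFD. The vessel growth factor Angpt1 (-1.15 ± 0.18, adjusted p = 0.0016, 10 of 10 slides), Elovl6 (-1.13 ± 0.26), Tmem79 (-1.10 ± 0.20), the mitochondrial gene Chchd10 (-1.09 ± 0.23) and Parm1 (-1.02 ± 0.22) had the most negative. Markers of lipid-laden macrophages, Gpnmb (0.96 ± 0.22), Atp6v0d2 (0.66 ± 0.12) and Mmp12 (0.58 ± 0.11), and the immediate early gene Atf3 (0.74 ± 0.13) differed upward. The other Atp6v0d2 probe gave 0.27. The Mmp12 probe was well above background on 4, 5 and 1 of 10 arrays of the 5-day LFD, 5-day HFD and 12-week LFD groups and on 10 of 10 of the 12-week HFD group, so its size is that of a signal near background in 3 groups. The differences for Lep (0.44 ± 0.35), Mest (0.39 ± 0.33), Fasn (-0.46 ± 0.32), Scd1 (-0.78 ± 0.27), Slc2a4 (-0.42 ± 0.14) and Itgax (0.55 ± 0.14) did not pass. Lnx2 (0.26 at 5 days, -0.10 at 12 weeks) and Slc4a11 (-0.29 and 0.17) were called at 5 days and in the interaction but not at 12 weeks. The count was 1066 with array weights, 929 with the epididymis and germ cell list means as covariates and 325 with no background subtraction. It was 6 without the arrays that carried epididymis transcripts, 31 without those and the germ cell arrays, 32 with scale normalization, 20 from the red channel alone, and between 37 and 299 as each slide was left out.

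Among the lists, 14 differed between the durations, 8 upward and 6 downward, and none held with an estimated correlation. De novo lipogenesis (median -0.48, adjusted p = 4.65e-08), cholesterol synthesis (-0.43, 9.33e-09), and the TCA cycle and oxidative phosphorylation (-0.26, 2.37e-10) were lower by more at 12 weeks, each with adjusted p = 0.298 with an estimated correlation. Of their genes 2 of 16 (4 adjusted over the list alone), 0 of 25 (12) and 2 of 23 (10) passed, Acacb (-0.83 ± 0.20), Cox6a1 (-0.44 ± 0.10) and Cox5a (-0.41 ± 0.09) among them. The other Acacb probe gave -0.46. Fat expansion genes (0.395), macrophages (0.31), lipid-associated macrophages (0.30) and resident macrophages (0.25) were higher by more, with 3 of 14 lipid-associated genes past the test (7 adjusted over the list alone) and adjusted p = 0.345, 0.345, 0.298 and 0.345 with an estimated correlation. Smaller differences were found for fatty acid oxidation (-0.19), extracellular matrix (0.17), the unfolded protein response (0.26), brown and beige adipocytes (-0.31), and T and NK cells (0.07), with adjusted p = 0.579, 0.579, 0.536, 0.58 and 0.579 with an estimated correlation. The mural cell list (-0.75) and the testis germ cell list (1.45) also differed (adjusted p = 0.345 and 0.579 with an estimated correlation). The mural value was 0.17 (adjusted p = 0.15) without the arrays that carried epididymis transcripts, and the brown and beige value was -0.02 (adjusted p = 0.75) there. The brown and beige call was lost without any 1 of 15 of the 40 arrays, with -0.088 (adjusted p = 0.168) without 12-week LFD replicate 10. The T and NK call was lost without any 1 of 20 arrays, with 0.033 (adjusted p = 0.181) without 12-week HFD replicate 9, and its value was 0.11 without 5-day HFD replicate 2. Without 5-day LFD replicate 5 the unfolded protein response had 0.15 (adjusted p = 0.0548) and the germ cell list 0.96 (adjusted p = 0.0326).

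On LFD, 3989 genes differed between 12 weeks and 5 days, 1351 higher and 2638 lower at 12 weeks (66.1% lower), and 102 changed more than 2-fold. Of those with a gene symbol 1155 were higher and 1315 lower. The comparison of durations on LFD holds what age, feeding time and any switch to the purified diet changed together. The lipid-droplet gene Cidea rose most, by 1.83 ± 0.35 (adjusted p = 0.000181, 10 of 10 slides), followed by Golga7b (1.72 ± 0.21, whose probes disagreed), Mal2 (1.70 ± 0.39), Mfsd2a (1.46 ± 0.48) and Fhod3 (1.28 ± 0.45). Without the arrays that carried epididymis transcripts Mfsd2a and Fhod3 had values of 0.05 and 0.44 (adjusted p = 0.937 and 0.441). Wfdc21 (-1.83 ± 0.17, adjusted p = 6.05e-09, 10 of 10 slides), Smo (-1.45 ± 0.36), Serpina3k (-1.42 ± 0.24), Mup19 (-1.36 ± 0.48) and Sly (-1.35 ± 0.14) fell most. Smo was measured by a repeat probe and had a value of 0.23 once the repeat-probe mean was a covariate. Of the 223 genes measured by repeat probes 70.0% passed the test, 155 of 156 of them lower, against 17.0% of the other genes. With the repeat-probe mean as a covariate 56.0% of 4081 calls were lower. The count was 981 without the arrays that carried epididymis transcripts, 1459 without those and the germ cell arrays, and 1652 (77.2% lower) from the red channel alone.

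Matrix genes fell with time on LFD, 17 of 28 in the list (20 adjusted over the list alone), with Col3a1 (-1.27 ± 0.15), Col1a1 (-1.21 ± 0.12) and Sparc (-1.01 ± 0.13) lower on 10 of 10 slides (median -0.55, adjusted p = 4.15e-13, and 0.175 with an estimated correlation). Cell cycle genes fell too, 10 of 19 (13 adjusted over the list alone), with Mki67 (-0.89 ± 0.14) and Birc5 (-0.88 ± 0.16) lowest (median -0.26, adjusted p = 7.35e-07, and 0.662 with an estimated correlation). Interferon genes (6 of 16 lower, median -0.165) and the progenitor and fibroblast list (4 of 13 lower, -0.20) shifted down, each with adjusted p = 0.662 with an estimated correlation. The macrophage (-0.16) and resident macrophage (-0.19) lists and the endothelial list (-0.19) also shifted down, with adjusted p = 0.757, 0.662 and 0.757 with an estimated correlation. With the repeat-probe mean as a covariate the macrophage value was 0.00204 (adjusted p = 0.90) and the endothelial value -0.0169 (0.93). De novo lipogenesis (4 of 16 higher, median 0.31, Scd2 0.97 ± 0.28, Scd1 0.83 ± 0.19), cholesterol synthesis (8 of 25 higher, 0.25) and the TCA cycle and oxidative phosphorylation (6 of 23 higher, 0.18) shifted up, each with adjusted p = 0.662 with an estimated correlation. So did oxidative stress defence (5 of 17 higher, 0.18, Gclc 0.41 ± 0.07), fatty acid oxidation (0.09), brown and beige adipocytes (0.345), B and plasma cells (0.255) and mast cells (0.32), with adjusted p = 0.0876, 0.757, 0.757, 0.662 and 0.662 with an estimated correlation. The B cell and mast cell values were each 0.06 (adjusted p = 0.81) without the arrays that carried epididymis transcripts. Of these calls 7 were lost without single arrays among the 20. These were brown and beige adipocytes (8 arrays, 0.14 without 12-week LFD replicate 10), endothelial cells (7, -0.12 without the same array) and macrophages (5, -0.14 without 5-day LFD replicate 7). They were also fatty acid oxidation (4, 0.063 without 5-day LFD replicate 5), progenitors and fibroblasts (4, -0.19 without 12-week LFD replicate 3), B and plasma cells (2, 0.196 without 12-week LFD replicate 8) and mast cells (2, 0.27 without 12-week LFD replicate 10). Fatty acid oxidation was 0.14 without 12-week LFD replicate 2 and progenitors and fibroblasts -0.13 without 5-day LFD replicate 8, both past the test. Lep (0.11 ± 0.25), Fasn (0.30 ± 0.22), Mest (-0.49 ± 0.24) and Ccl2 (-0.33 ± 0.19) did not pass.

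On HFD, 1586 genes differed between 12 weeks and 5 days, 697 higher and 889 lower at 12 weeks, and 30 changed more than 2-fold. The count was 3132 with array weights, 2815 with the repeat-probe covariate, 673 with scale normalization, 578 from the red channel alone and 1051 without slide 9. Sfrp5 (2.82 ± 0.23, adjusted p = 1.18e-10), Thbs1 (2.23 ± 0.24), Prr32 (2.09 ± 0.17) and Ankrd29 (1.15 ± 0.16) rose on 10 of 10 slides. The germ cell gene Tnp1 (1.76 ± 0.55) rose as well, and had a value of 0.14 once the epididymis and germ cell list means were covariates. Tnp1 is a member of the germ cell list, so most of that shrinkage was fixed in advance. The liver-type secreted proteins Mup9 (-2.26 ± 0.60), Serpina3k (-2.20 ± 0.24), Mup19 (-1.89 ± 0.48), Serpina1a (-1.60 ± 0.45) and Serpina1c (-1.57 ± 0.42) fell most. In the cell cycle list 13 of 19 genes fell (17 adjusted over the list alone), Mki67 (-1.03 ± 0.14) and Birc5 (-0.89 ± 0.16) most (median -0.415, adjusted p = 1.28e-16, and 0.162 with an estimated correlation). In the matrix list 10 of 28 fell and 2 rose (median -0.27, adjusted p = 0.533 with an estimated correlation), with Col1a1 (-1.36 ± 0.13) and Col3a1 (-1.36 ± 0.15) lower. Lipid-associated macrophage genes rose, 6 of 14 (7 adjusted over the list alone), with Gpnmb (1.14 ± 0.15), Lgals3 (0.72 ± 0.12), Atp6v0d2 (0.60 ± 0.09) and Itgax (0.45 ± 0.10, adjusted p = 0.00382) higher (median 0.26, adjusted p = 3e-06, and 0.162 with an estimated correlation).

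The unfolded protein response (3 of 14 higher, median 0.17, Sdf2l1 0.63 ± 0.13) and fat expansion genes (2 of 11 higher, 0.24) also shifted up on HFD with time, with adjusted p = 0.411 and 0.576 with an estimated correlation. The macrophage (0.0975), mast cell (0.39), erythroid (0.37) and testis germ cell (1.55) lists did too (adjusted p = 0.768, 0.576, 0.533 and 0.533 with an estimated correlation). The germ cell value was 0.05 (adjusted p = 0.96) with the tissue covariates, which hold the mean of this same list and so remove its shift by construction. Interferon genes (3 of 16 lower, median -0.19, Isg15 -0.52 ± 0.10), branched-chain amino acid breakdown (-0.07, Mccc1 -0.51 ± 0.10), cholesterol synthesis (-0.15), de novo lipogenesis (-0.14), and the TCA cycle and oxidative phosphorylation (-0.08) shifted down, with adjusted p = 0.576, 0.768, 0.768, 0.768 and 0.866 with an estimated correlation. With time on HFD 6 of these calls were lost without single arrays among the 20. De novo lipogenesis (10 arrays) was -0.056 and -0.077 without 5-day HFD replicates 3 and 7, cholesterol synthesis (5) -0.088 without the former, and the TCA cycle and oxidative phosphorylation (10) -0.049 without the latter. Branched-chain amino acid breakdown (8) was -0.041, -0.038 and -0.036 without 5-day HFD replicate 3 and 12-week HFD replicates 1 and 4. The macrophage (3) and mast cell (7) lists had 0.076 and 0.34 without 5-day HFD replicate 7. Of the 16 lipogenesis genes 1 was called lower with time on HFD (2 adjusted over the list alone), and the lowest value was -0.55. Fasn at -0.17 ± 0.22 and Scd1 at 0.05 ± 0.19 did not pass. Lep (0.55 ± 0.25, adjusted p = 0.186), Adgre1 (0.23 ± 0.11) and Ccl2 (0.41 ± 0.19) did not pass.

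Across the 10 animals of a group, 1 of 12 relations between macrophage genes and adipocyte measures passed. On LFD at 12 weeks the macrophage list mean rose with Lep (Pearson r = 0.831, permutation p = 0.00264, adjusted p = 0.0317, Spearman rho = 0.879, permutation p = 0.00163, adjusted p = 0.0196). Without the 2 animals farthest from the median the r was 0.667. From the red channel alone it was 0.520 (adjusted p = 0.260), and as deviations from the slide mean 0.627 (adjusted p = 0.0974). Of the 10 arrays of that group 6 carried epididymis transcripts, and the relation was not tested without them. On HFD at 12 weeks the r was 0.526 (permutation p = 0.12, adjusted p = 0.280), and as deviations from the slide mean 0.807 (permutation p = 0.00513, adjusted p = 0.0616). The macrophage list and the mature adipocyte list on LFD at 5 days had r = 0.796 (permutation p = 0.0415, adjusted p = 0.138), which was -0.504 without the 2 farthest animals. On LFD at 12 weeks these lists had r = 0.660 (permutation p = 0.0373, adjusted p = 0.138), which was 0.144 without the 2 farthest animals.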

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

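The tests against a lower share of adipocyte RNA, and the fits that remove or adjust for epididymis, germ cell or repeat-probe signals, were chosen only after the results had been seen.

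The number of genes past the threshold was compared with that from splits of the same arrays drawn at random. In each of the 5 comparisons 1 of 100 splits, the real one itself, gave as many genes. That is the lowest share 100 splits can show, so chance is an unlikely source of these counts but is not excluded. The real counts and the highest of the other splits were 297 and 39 for diet at 5 days, 4329 and 937 for diet at 12 weeks, and 144 and 1 for the interaction. They were 3989 and 102 for time on LFD and 1586 and 1066 for time on HFD. Most other splits gave no gene, and for diet at 12 weeks 94 gave none while 4 gave more than 100.

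Within groups, 32 of the 215 combinations of a group and a measure had an animal far from the others by Dixon's test, where about 1 in 20, or 10.8, would be by chance. Of these, 15 were the same animal, replicate 5 of the 5-day LFD group. Its list means were -0.54 for triglyceride synthesis and lipid droplets, -0.35 for lipolysis, -0.38 for fatty acid oxidation, -0.16 for branched-chain amino acid breakdown and -0.47 for adipokines. They were -0.50 for extracellular matrix, 0.51 for the unfolded protein response, -0.50 for mature adipocytes, -0.55 for progenitors and fibroblasts, -0.65 for macrophages, -0.60 for resident macrophages and -0.56 for endothelial cells. The same animal had the highest epididymis (1.54) and testis germ cell (1.37) list means of its group and an Adipoq value of -0.71. Without its array the interaction had 294 genes, and the 5-day diet shift of the macrophage list was 0.10 in place of 0.18.

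In the 12-week HFD group, replicate 5 stood apart with Ucp1 at 3.66, brown and beige adipocytes at 1.21, fatty acid oxidation at 0.37, and the TCA cycle and oxidative phosphorylation at 0.068, all above the rest of its group. In the 12-week LFD group, replicate 10 had brown and beige adipocytes at 1.37, lipolysis at -0.38 and Pparg at -0.40, and replicate 6 had chemokines, cytokines and acute phase at -0.44 and lipid-associated macrophages at -0.36. In the 5-day HFD group single animals stood apart in cell cycle (0.86), resident macrophages (0.48), T and NK cells (0.37), neutrophils (0.31) and epididymis (0.39). Single values were also apart for Ccl2 in the 5-day LFD group (1.07), and for T and NK cells (0.43) and Pparg (-0.86) in the 12-week HFD group. Some of these arrays were among those counted as carrying epididymis or germ cell transcripts. They were 12-week LFD replicates 6 and 10 and the 12-week HFD arrays apart in T and NK cells and Pparg. Apart from the array with the epididymis value, the others, such as 12-week HFD replicate 5, were not. No explanation was tested for these animals.

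The diet effect differed between 5 days and 12 weeks, by a test of the difference itself, for the following named genes. It was more positive at 12 weeks for Sfrp5 (2.55), Thbs1 (2.11), Ifi27l2a (1.26), Ankrd29 (1.24), Prr32 (1.21), Gpnmb (0.96), Retnla (0.86), Atf3 (0.74), Atp6v0d2 (0.66), Klf4 (0.64), Mmp12 (0.58) and Col18a1 (0.41). The Mmp12 probe was near background in 3 of the 4 groups, well above it on 4, 5 and 1 of 10 arrays, so the size of its difference is uncertain. It was more negative for Angpt1 (-1.15), Elovl6 (-1.13), Tmem79 (-1.10), Chchd10 (-1.09), Parm1 (-1.02), Acacb (-0.83), Egln3 (-0.55), Cox6a1 (-0.44) and Cox5a (-0.41).

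Among lists the median difference was -0.48 for de novo lipogenesis, -0.43 for cholesterol synthesis, -0.19 for fatty acid oxidation, -0.26 for the TCA cycle and oxidative phosphorylation, -0.31 for brown and beige adipocytes and -0.75 for mural cells. It was 0.39 for fat expansion genes, 0.17 for extracellular matrix, 0.26 for the unfolded protein response, 0.31 for macrophages, 0.30 for lipid-associated macrophages, 0.25 for resident macrophages, 0.069 for T and NK cells and 1.45 for testis germ cells. None of these held with an estimated correlation, and 4 of the 14 did with fry. The brown and beige value was -0.088 (adjusted p = 0.168) without 12-week LFD replicate 10 and the T and NK value 0.033 (adjusted p = 0.181) without 12-week HFD replicate 9, and each call was lost without any 1 of 15 and 20 arrays. The T and NK value was 0.11 without 5-day HFD replicate 2. Without 5-day LFD replicate 5 the unfolded protein response had 0.15 (adjusted p = 0.0548) and the germ cell list 0.96.

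Most genes that differed with time on LFD were lower at 12 weeks, by a median of -0.30 for the 2638 that fell. Among called genes with a gene symbol the excess was smaller, with 1315 lower and 1155 higher. Epididymis or testis tissue in the arrays counted as carrying such transcripts is argued against as the whole source, since 85.0% of that median was kept without them. All 2638 genes kept their sign, but they were chosen on data that include the arrays kept, which makes this likely in advance. Lower levels of such tissue in the arrays kept were not tested, and some of its genes were well above background there. A signal shared with CA or TG repeat probes stays open. With the mean of those probes as a covariate 59.3% of the median was kept (-0.30 became -0.18), and 2450 of the 2638 genes kept their sign. Age and time on the diet, which the design changes together, are also open and were not tested apart.

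Macrophage genes were higher on HFD at 12 weeks, with a list mean 0.47 ± 0.05 above LFD (SE, n = 10 per group). A lower share of adipocyte RNA would raise the markers of other cells alike, but the macrophage list rose by 0.38 ± 0.08 more than the endothelial list, which differed by 0.09 ± 0.10. Other cell lists did not all behave like the endothelial list. Their mean change was 0.32 for progenitors and fibroblasts, 0.15 for T and NK cells and -0.63 for mural cells. The endothelial comparison therefore cannot exclude a lower adipocyte share as part of the source. Neighbouring tissue is argued against, with 98.5% of the difference kept without those arrays (0.46 ± 0.08, 4 LFD and 5 HFD animals). The repeat-probe signal is argued against as well, with 83.6% kept. These values are consistent with more macrophages, or more macrophage transcripts per cell, on HFD, which stays a hypothesis because it was found and tested on the same arrays.

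Lipogenic genes were lower on HFD at both durations. A lower share of adipocyte RNA is argued against, since the lipogenesis list mean fell below the mature adipocyte list mean by a difference of -1.06 ± 0.14 at 5 days and -1.62 ± 0.11 at 12 weeks (SE, n = 10 per group). The mature adipocyte list itself differed by -0.09 ± 0.10 and -0.07 ± 0.10. Without the arrays that carried epididymis or germ cell transcripts 94.6% of the difference was kept at 5 days and 105% at 12 weeks. A lower expression of these genes within adipocytes on HFD stays a hypothesis, because whole tissue was measured and not adipocytes alone.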

How the results depend on the processing

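The fits without arrays that carried epididymis or germ cell transcripts, with their list means or the repeat-probe mean as covariates, without repeat probes, and without single arrays were chosen only after the data had been seen. Where no cause is given below, the cause was not tested.

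Of 370 values of named genes, 320 of them calls, between 302 and 337 kept their direction and side of the threshold as each slide was left out. With no background subtraction 360 did, with the scanner software's ratio 345, with array weights 346, with a trended and robust prior 363 and with values from the series table it was 319 of 366. With the red channel alone 248 did and with scale normalization 189. A-quantile normalization leaves the log ratios as they are and so tests nothing. The share of 5-day calls that were called in the same direction at 12 weeks was 89.5% with scale normalization, 89.0% with array weights and 90.8% to 98.4% as each slide was left out.

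Scale normalization gave 19 genes for diet at 5 days (68.4% lower), 2643 at 12 weeks, 32 for the interaction (28.1% lower) and 673 for time on HFD. The red channel alone gave 90, 2255, 20 (30% lower) and 578, and 1652 for time on LFD (77.2% lower). Array weights gave 873 for diet at 5 days, 1066 for the interaction and 3132 for time on HFD. No background subtraction gave 325 for the interaction, and the series table gave 25.5% lower there. A fit on only the groups compared, which has fewer arrays to estimate the spread, gave 172 for diet at 5 days.

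Without the 12 arrays that carried epididymis transcripts there were 89 genes for diet at 5 days, 2007 at 12 weeks (62.2% lower), 6 for the interaction and 981 for time on LFD, in smaller groups of 4 to 8 animals. Without the 15 arrays with either kind of transcript there were 109, 2533, 31 and 1459. With both list means as covariates the interaction had 929. With the repeat-probe mean as a covariate diet at 5 days had 474 and time on HFD 2815, and 56.0% of 4081 genes were lower with time on LFD.

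The correlation across genes between the diet effects was 0.0451 with the scanner software's ratio, 0.0745 with the list means as covariates and 0.769 among genes called at either duration, a choice that raises it. Macrophage genes and Lep on LFD at 12 weeks correlated at 0.520 in the red channel and 0.627 as deviations from the slide mean, neither past the test. With an estimated correlation 1, 6, 0, 0 and 0 lists were called for diet at 5 days, diet at 12 weeks, the interaction, time on LFD and time on HFD, where camera without it called 16, 19, 14, 15 and 14. With fry there were 10, 22, 4, 12 and 7 in that order.

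Some medians, or the direction of a list's test, turned. With time on LFD and the repeat-probe covariate, Smo was 0.23, Ciita 0.056, Vegfa 0.024 and Itgam 0.089, and the macrophage list 0.00204. The endothelial list shrank to -0.0169, where only the direction of its test turned. Itgam was 0.020 without repeat probes. It did not turn as each slide was left out, where its lowest value was -1.25. In the interaction, the mast cell list was 0.42 and the mural cell list 0.17 without the epididymis arrays, and the brown and beige list and the mural list were 0.0705 and 0.0704 without either kind. The mural list was -0.24 with time on LFD in both of these fits. With the tissue covariates, the branched-chain amino acid list was 0.040 with time on HFD. The testis germ cell list shrank from 1.55 to 0.048, where only the direction of its test turned. Its own mean was among the covariates, so this shrinkage was fixed in advance.

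Leaving out 1 slide or 1 array gave 119 to 428 genes for diet at 5 days, 3356 to 4897 at 12 weeks, 37 to 299 for the interaction, 3042 to 4302 for time on LFD and 1051 to 1772 for time on HFD, and the correlation across genes was 0.178 to 0.461. Diet at 5 days had 158, 122, 128 and 119 genes without slides 1, 8, 9 and 10, and 174, 194, 147 and 150 without 5-day LFD replicates 1, 9 and 10 and 5-day HFD replicate 8. The interaction had 299, 38, 235, 47, 41, 37 and 39 without slides 1, 3, 4, 6, 7, 8 and 9. It had 95, 294 and 78 without 5-day LFD replicates 4, 5 and 9, and 76, 87 and 86 without 5-day HFD replicates 5, 7 and 9. It had 89, 88 and 93 without 12-week LFD replicates 6, 7 and 8, and 277, 93, 280, 85 and 72 without 12-week HFD replicates 1, 3, 4, 8 and 10. Time on HFD had 1051 without slide 9.

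With the slide as a replicate block there were 339, 4447, 174, 4125 and 1636 genes in the 5 comparisons, and 355 of the 370 named values kept their call. Among those that lost it in limma were Cavin1, Fn1 and Bnip3 for diet at 5 days (adjusted p = 0.0561, 0.0507 and 0.0507). Klf4 lost its call in the interaction (adjusted p = 0.0533). The mural list passed for diet at 12 weeks (adjusted p = 0.0447), and the brown and beige list for time on LFD (0.0603) and the TCA cycle list for time on HFD (0.0505) did not. After group means were taken out, arrays of 1 slide correlated at -0.515 to 0.655 (mean 0.0287, 29 of 60 pairs above 0.1). Arrays of different slides and groups correlated at -0.690 to 0.790 (mean 0.00239, 200 of 540 pairs above 0.1). Same-slide pairs were thus slightly more alike on average, but not every sample correlated best with its own number. In signal the slides did differ, with a median red signal above background of 45.5 to 75.1 on every array of slides 1 to 5 and 89.0 to 123 on every array of slides 6 to 10, and each slide holds all 4 groups. The share of probes well above background, 57.1% to 74.0% per array, limits what can be measured of dim genes.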

Other observations

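The repeat-probe values and the limits that mark an array as carrying epididymis or germ cell transcripts were chosen only after the data had been seen.

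The largest source of variation between arrays was not diet. The first principal component held 27.0% of the variance and correlated with the mature adipocyte list mean in size at 0.843 and with the repeat-probe mean at 0.602. The second held 15.3% and correlated with the epididymis list mean at 0.705.

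The group of probes with a CA or TG repeat was tight within groups. Of them, 62.7% correlated with their own mean above 0.8, against 2.12% of other probes. Of the 223 genes they measured, limma called 156 with time on LFD, 26 with diet at 12 weeks and 5 with time on HFD. These were 70.0%, 11.7% and 2.24%, against 17.0%, 19.1% and 7.02% of other genes. It called 0 with diet at 5 days and 0 in the interaction. There only 1.32% and 0.639% of other genes were called, so few calls could be awaited among 223. Their median log2 difference was 0.319 with diet at 12 weeks and 0.388 in the interaction, so the absence of calls does not show those comparisons free of the signal.

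The 10 epididymis genes and 9 testis germ cell genes are in no other list. Among the arrays counted as free of the signal, 6 of the 10 epididymis genes were well above background on all 28 arrays, and 6 of the 9 germ cell genes on all 31. Lcn5 and Adam7 reached red signals of 16.3 and 15.2 on the log2 scale.

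Once sampling error was allowed for, the correlation across genes between the diet effects at 5 days and 12 weeks was 0.639, with 0.311 to 0.996 as each slide was left out. Regroupings of the animals gave uncorrected correlations of -0.702 to 0.654, where the real uncorrected value was 0.347, and the corrected value was not computed for regroupings.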
